A study of Arabidopsis thaliana with 4 samples.

How the data were processed

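RNA came from whole 10-day-old seedlings, 2 wild type and 2 OsRR6ox samples, each labelled by the submitters as a biological replicate. Whether the replicates were grown at different times is not given in the sources used here, so p-values measure the spread between these samples. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled by the Affymetrix 3′ IVT method. The authors deposited 1 table of log2 expression values, 22810 probe sets by 4 arrays. R 3.4.0 is named in the submitters' processing notes. The background correction, summarisation and normalization behind the deposited log2 values are not given in the sources used here, and a correction that assumes equal total signal would hide a shift common to all genes.

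Of the probe sets, 64 are array controls and stayed out of the tests, which left 22746. Gene names came from the platform annotation and were updated through gene identifiers to the TAIR10.1 reference table. A single gene is given for 13513 probe sets, several for 503 and none for 8730, which are unnamed here. Of the first, 13436 matched the reference table, and the others kept the platform's symbol. Together the 13513 stand for 13355 genes. No probe set with several genes was named. Where a gene has several probe sets, the probe set with the highest mean over all arrays stood for it in the lists. Of the 13355 genes, 147 have more than 1 probe set, and in 5 of them a probe set passed the test. Probe sets of 1 gene could disagree, as for nad1, where the probe set that passed differed by 1.95 and the one that stood for it in the lists by -0.42.

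The genotypes were compared on the deposited log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, moderated test, two-sided), with Benjamini-Hochberg adjustment over 22746 probe sets and a threshold of 0.05. Lists of at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over 12 lists, with an estimated correlation and fry beside it. The other lists had fewer measured members (25 lists) or none (11 lists), of 48 fixed before the data were examined. Few members were measured under a single gene name with a symbol, which limits most lists. List members were also adjusted over their own list alone. This looser threshold was not part of the fixed plan and was not corrected across lists, some of which share genes. As 3407 of 22746 probe sets had an unadjusted p under 0.05 (limma), such calls can be met in any list. The organelle lists were fixed by locus code, which the reference table writes differently, so plastid genes were taken from its plastid chromosome and mitochondrial genes by symbol (nad, cox, ccb, matR, orfX, cob).

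Named genes were chosen by a rule fixed before the data were examined. It took up to 15 genes with the largest rise and 15 with the largest fall among probe sets past the threshold with exactly 1 gene and a symbol, whose arrays did not overlap between genotypes, plus the members of each list with the smallest p and all measured type-A response regulators. Here 15 rose and 14 fell. Array background was taken as the lowest 25% of probe sets on each array, and the absent trp controls averaged 3.58 to 3.60. Detection calls were not used here. The number of arrays limits the precision, with a median residual SD of 0.145 on the log2 scale and 3.17 prior degrees of freedom.

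Alternatives fixed before the data were examined were quantile normalization, median centring, leaving out dim probe sets, other variance models, array weights, the replicate number as a block, other thresholds, other list tests and leaving out each array. Centring on 42 spike-in controls, pooled over all their types, and leaving out probe sets on in a single genotype, were added after the data were seen. The fits were tested on simulated data with the 22746 probe sets of this comparison. Noise was drawn independently for each probe set, with variances from the model fitted to these data. The rates that follow thus hold under that model and are not error rates of the real arrays. Of the probe sets changed 2-fold 24% were recovered, of those changed 4-fold 95% and of those changed 8-fold 94%, with 8 false calls among 162. In the simulated lists, 1 unshifted list was called beside the shifted one.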

Results

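Transcript levels were measured in whole 10-day-old Arabidopsis thaliana seedlings of accession Col-0 on 4 Affymetrix ATH1 arrays, 2 from the wild type and 2 from OsRR6ox. OsRR6ox seedlings over-express OsRR6, a rice type-A response regulator, one of the small receiver-domain proteins that act in cytokinin signalling. No probe set used here is annotated to the rice transgene, so its level was not measured. Array medians lay between 6.71 and 6.81 on the log2 scale. Pearson's r across probe sets was 0.989 between the wild type arrays and 0.992 between the OsRR6ox arrays, against 0.976 to 0.980 between genotypes. Probe sets are not independent replicates, and no pair of arrays held identical values at more than 0.127% of probe sets.

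The comparison of OsRR6ox with wild type asked which transcripts differ in seedlings that over-express this regulator. The gene with a symbol and the largest measured rise was ECS1, which encodes a cell wall-associated protein. It stood at 5.14 ± 0.33 in the wild type and 11.72 ± 0.17 in OsRR6ox (log2, mean ± SD, n = 2 each), a rise of 6.57 or 95.1-fold. ZW9 rose by 4.06, although its wild type arrays read 6.59 and 4.96, and the cytochrome P450 gene CYP71B34 rose by 3.45 from near array background. The MADS-box gene AGL87 rose by 2.83, and the ubiquitin ligase gene LUL1 by 2.09. Genes for subtilases, a family of secreted proteases, moved in both directions, with SBT4.12 up 4.66-fold, ATSBT5.2 up 2.82-fold and SBT3.12 down 2.55-fold.

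Further genes that rose were MOB1-like by 2.03, CcdA, a thylakoid protein of cytochrome assembly, by 1.83, and RALFL32, a RALF-like signalling peptide, by 1.32. EXPA7, an expansin of root hairs, rose by 1.39. FHL, which acts with FHY1 in nuclear import of phytochrome A, rose by 1.38, from 4.03 ± 0.08 to 5.41 ± 0.00 (SD, n = 2 each). CP5 rose by 1.02 and the glycosyltransferase gene UGT71C3 by 1.01. For nad1, a mitochondrial gene of respiratory complex I, a single probe set rose by 1.95, while the other 6 differed by -0.42 to 0.02 and did not pass.

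Of the 14 genes with a symbol that fell, 5 are plastid-encoded. The plastid ribosomal protein gene rps14 differed by -3.17, ndhF by -2.64, petN by -2.09, rpoC2 by -1.57 and ndhG by -1.32. Nuclear genes that fell included CW9, a gene of the NBS-LRR resistance class, at -2.04, and the ubiquitin ligase gene RING1 at -1.46. LHCB4.3, an isoform of the photosystem II antenna protein CP29, fell from 10.30 ± 0.19 to 8.89 ± 0.04 (SD, n = 2 each), a difference of -1.41. UPB1, a bHLH factor of the transition from division to elongation in the root, differed by -1.34. The glycosyltransferase genes UGT84A1 and UGT87A2 differed by -1.36 and -1.34, NDP1 by -1.26 and REV7, which encodes a subunit of DNA polymerase zeta, by -1.10.

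**Figure D1:**
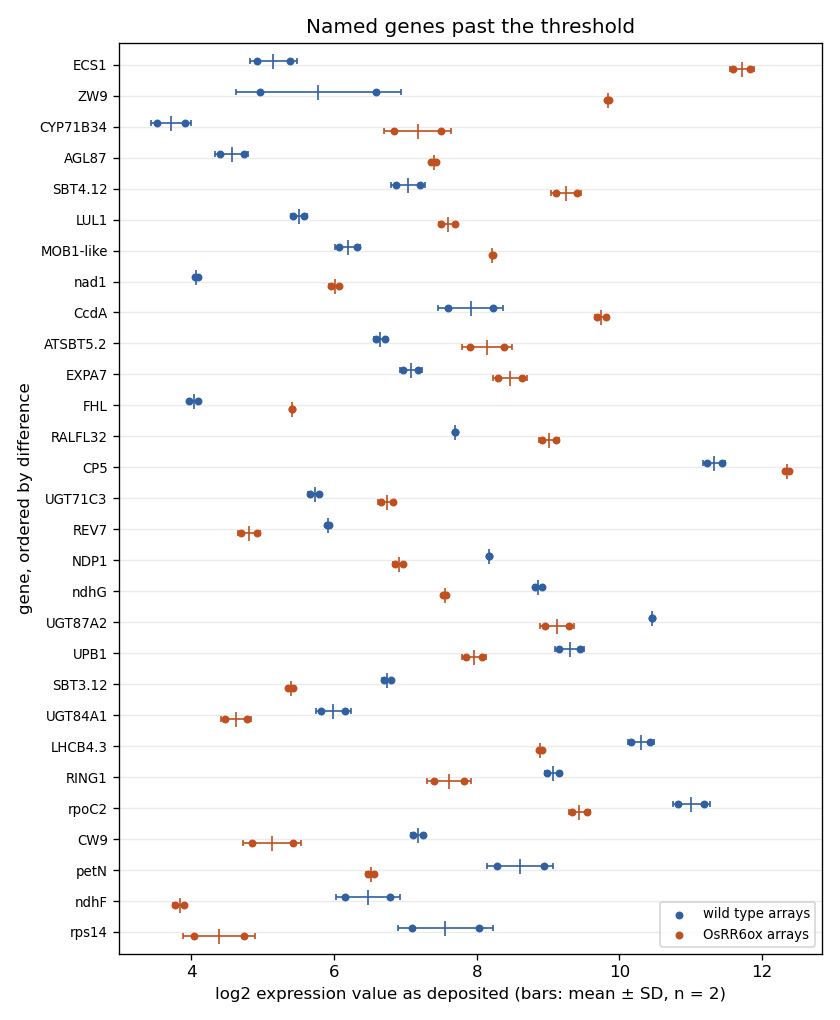
Deposited log2 values (horizontal axis) of the 29 genes with a symbol that passed the test, with a dot per array, and bars for the mean ± SD of 2 arrays per genotype. In all 29 the arrays of the genotypes do not overlap, from ECS1 at a difference of 6.57 to rps14 at -3.17.

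Several of the largest measured changes belonged to genes known here by a locus code alone, which were chosen after their values were seen. AT2G25510 rose by 7.09, AT1G23960 by 5.57 and AT5G45500 by 4.22, and AT3G43740 rose 17.1-fold. AT3G44630, of the TIR-NBS-LRR class of immune receptors, rose by 3.72, and AT4G16870, a copia-type retroelement, by 3.06. Methyltransferase genes of the SABATH type, AT5G04380 and AT5G38020, fell by 4.85 and 3.82. AT3G48640 fell by 5.67, AT3G28270 by 3.54, AT5G15360 by 3.22 and AT2G35820 by 3.06. AT5G47980, a BAHD acyltransferase gene of the thalianol cluster, fell by 2.39, and AT5G51470, a GH3-like gene, differed by -1.98. AT3G48640, AT5G04380 and ndhF lay at array background in OsRR6ox, and AT2G25510, AT1G23960, AT5G45500, AT3G43740, AT3G44630, CYP71B34, FHL and the nad1 probe set in the wild type, so their differences are lower bounds of the change.

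In total 296 of 22746 probe sets passed (limma, Benjamini-Hochberg adjusted p under 0.05), and 3407 had an unadjusted p under 0.05. Of these 185 rose and 111 fell, and 281 changed at least 2-fold. By gene, 179 of them have a single gene, 29 of these with a symbol, 21 have several genes and 96 are unnamed here. All 296 had arrays that did not overlap between genotypes, as did 46.1% of all probe sets tested, where chance gives 33.3%. Rises made up 62.5% of the calls as deposited, and 2863 of 3013 calls after centring on the spike-in controls. That alternative, chosen after seeing the data, moved the median of all probe sets to 0.49 from -0.04. That fit gave all probe sets a common SD of 0.294 (infinite prior degrees of freedom, against 3.17 as deposited), so its number of calls is not comparable with the 296. Without OsRR6ox replicate 1 there were 51 calls, with 1 of the 29 genes among them, without OsRR6ox replicate 2 there were 45, with 2 of the 29, and without wild type replicate 2 there were 465, with 21 of the 29 and 46.7% of calls rising.

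Most genes of the organelle genomes had lower values in OsRR6ox as deposited, while spike-in centring, which shifts all probe sets alike, brought the list means to 0.00 and 0.14. The spike-in controls averaged 8.80 and 9.14 on the wild type arrays and 8.45 and 8.43 on the OsRR6ox arrays. That reference thus itself varied between the wild type replicates. Single spike-in controls differed between genotypes by -0.13 to -0.91, OsRR6ox minus wild type. The list means under this centring, and their sign, therefore depend on which controls are pooled. Of 69 plastid-encoded genes measured, 58 had a lower mean in OsRR6ox, 5 fell and 0 rose, with a mean difference of -0.52 and a median of -0.39. The 5 were rps14, ndhF, petN, rpoC2 and ndhG, which differed by -2.65, -2.11, -1.57, -1.04 and -0.79 after spike-in centring. There ndhG no longer passed (limma adjusted p = 0.0530). Adjusted over the list alone, 20 fell and 1 rose, psbK, at 0.90. Among members short of the threshold over all probe sets, petD of the cytochrome b6f complex differed by -2.52 and atpI of the ATP synthase by -1.02. Of 16 mitochondrion-encoded genes, 13 had a lower mean in OsRR6ox and 0 passed, with a mean of -0.39 and a median of -0.43. Here nad1 stands by its brightest probe set, at -0.42, and not by the one that rose. Adjusted over the list alone, 3 fell, nad4L at -1.06, nad9 at -0.83 and nad5 at -0.67.

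Against all other genes, camera with a preset correlation of 0.01 gave an adjusted p of 2.96e-10 for the plastid list and 0.0019 for the mitochondrial list. With an estimated correlation neither held, at camera adjusted p = 0.373 and adjusted p = 0.529. The estimated correlations were 0.0212 and 0.0342. That setting also rests its p-value on the few residual degrees of freedom of 4 arrays, so correlation between genes was not shown to account for the loss. Fry, which tests a list against no change and not against other genes, gave an adjusted p of 0.0582 for both lists. Relative to the mean of all probe sets of the same array, which a shift of a whole array leaves alone, the plastid mean differed by -0.49 ± 0.05 and the mitochondrial mean by -0.36 ± 0.07 (SE over arrays, n = 2 each). The ribosomal RNA controls had lower means in OsRR6ox, although 25S varied widely between the wild type arrays and nearly met between genotypes. The 25S control read 7.41 and 9.94 in the wild type and 6.45 and 7.41 in OsRR6ox, and the 5S control 5.59 and 4.88 against 3.73 and 3.74, the latter at array background. The ubiquitin control, in which a larger 3′ minus 5′ gap marks shorter labelled RNA, gave gaps of 1.83 and 1.77 in the wild type and of 1.21 and 1.25 in OsRR6ox. In 5 of 6 such control sets the gap was smaller on both OsRR6ox arrays than on both wild type arrays. Mean gaps differed by -0.15 for GAPDH and by -0.25, -0.11 and -0.25 for a second set of ubiquitin, GAPDH and actin, whereas the first actin set overlapped between genotypes (2.95 and 2.59 against 2.62 and 2.77).

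**Figure D2:**
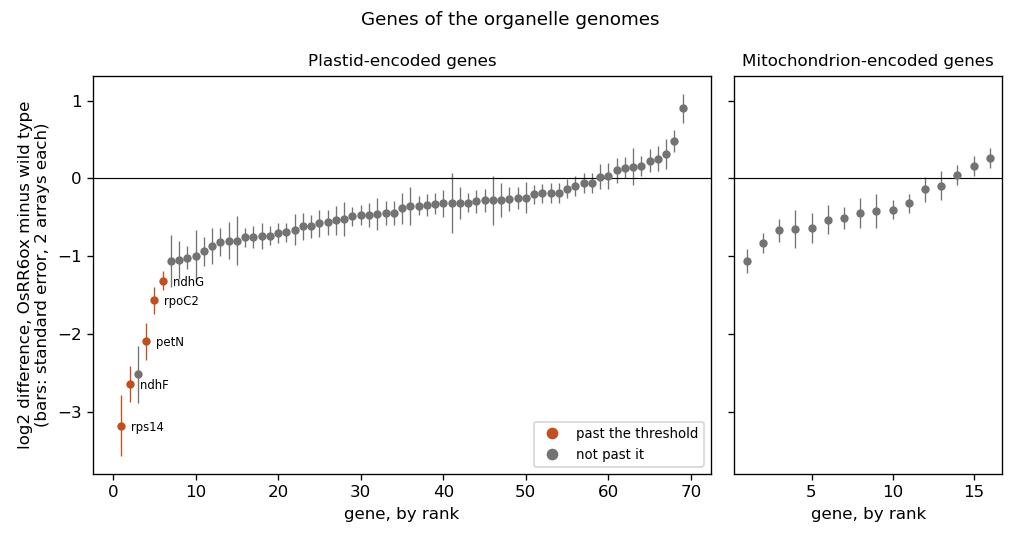
Log2 difference, OsRR6ox minus wild type (vertical axis), of 69 plastid-encoded and 16 mitochondrion-encoded genes ranked by difference, with the standard error of 2 arrays per genotype, from values as deposited. Genes past the threshold are named, and 58 plastid and 13 mitochondrial genes lie below 0, although spike-in centring moves the means of both lists to 0.00 and 0.14.

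Few cytokinin genes were measured under a single gene name. They were 2 of 10 type-A regulators, 1 of 10 type-B regulators and 2 of 27 genes of cytokinin synthesis, activation and breakdown. A lack of calls among them thus does not show that the cytokinin response was unchanged. The type-A response regulators RR16 and ARR15 differed by -0.39 and -0.15, and neither passed. The type-B regulator RR18 differed by -0.09, and the cytokinin glucosyltransferase genes UGT76C2 and UGT76C1 by -0.10 and -0.07, also short of the threshold. RR18 lay at array background on all 4 arrays and ARR15 on both OsRR6ox arrays, so their differences carry little information. Cytokinin receptors and phosphotransfer proteins, cytokinin response factors and brassinosteroid genes had 0 members measured under a single gene name. Of 8 auxin genes 0 passed, YUC2 at -0.43 and IAA20 at -0.37 having the smallest p, and camera gave an adjusted p of 0.495 for the list. The gibberellin receptor genes GID1A, GID1C and GID1B differed by 0.16, 0.15 and -0.17, and EIN3, of the ethylene list, by 0.18, with 0 passing.

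Light-related genes gave single calls. FHL rose and HYH, a bZIP factor related to HY5, differed by -0.64 without passing. Of 3 light-harvesting genes LHCB4.3 fell, while its paralogs LHCB4.2 and LHCB4.1 were at 11.37 and 13.08 in the wild type and 12.57 and 13.25 in OsRR6ox and did not pass over all probe sets. Adjusted over the list alone, LHCB4.3 fell and LHCB4.2 rose. Of 6 chlorophyll synthesis genes 0 passed, with PORB at 0.55 and CHLI2 at -0.36 (camera adjusted p = 0.573). The clock gene GI differed by 0.08, and the flowering genes AGL24 and LD by 0.41 and -0.09. Flavonoid and anthocyanin genes showed 0 calls among 6, UGT78D2 at -0.34 and DFR at -0.31 (camera adjusted p = 0.643).

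No stress or defence list held a gene past the threshold over all probe sets. Few of their members were measured, so this does not show that such a response was absent. Measured were 4 of 17 cold, 2 of 29 dehydration, 4 of 33 jasmonate, 3 of 25 salicylic acid and defence and 4 of 28 heat genes. In the cold list COR15B differed by 1.66, COR15A by 0.40, COR47 by -0.76 and STZ by -0.46, and adjusted over the list alone 2 rose and 1 fell. COR47 and LTI30 of the dehydration list differed by -0.76 and -0.71. The defensin genes PDF1.2 and PDF1.2b of the jasmonate list stood at 5.17 and 6.50 in the wild type and 6.67 and 7.16 in OsRR6ox, and 1 rose when adjusted over the list alone. Among salicylic acid and defence genes WRKY53 and GRX480 differed by -0.64 and -0.66. WRKY53 and WRKY6 of the senescence list differed by -0.64 and -0.33, and the WRKY family of 6 had a camera adjusted p of 0.936. The ascorbate peroxidase gene SAPX differed by -0.82 and the glutathione reductase gene GR by -0.38, and 1 of 3 antioxidant genes fell when adjusted over the list alone. HSA32 and Fes1A of the heat list differed by -0.40 and -0.15, and CML37, at background on all arrays, and STZ of the touch list by -0.34 and -0.46.

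BHLH101 and PYE, regulators of iron homeostasis, differed by 2.66 and 0.64, and AT3G13610, of the same list, by -0.85, with 0 of 3 passing over all probe sets and AT3G13610 falling when adjusted over the list alone. The values of BHLH101 and PYE rest on wild type replicate 1, without which BHLH101 differed by 0.52 and PYE by 0.00. Tau-class glutathione transferases showed 0 calls among 11, GSTU22 at -1.14 and GSTU16 at -0.81, both of which fell when adjusted over the list alone (camera adjusted p = 0.643). In the phi class ATGSTF13 differed by 1.26 and GSTF4 by -0.42, and ATGSTF13 rose when adjusted over the list alone. Of 7 calmodulin-like genes CML41 differed by -1.34 and CML30 by 0.33, with 1 fall adjusted over the list alone (camera adjusted p = 0.609).

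In the cell wall families EXPA7 was the single call. It was 1 of 14 expansins, of which EXPA18 differed by 1.11 and EXPA8 by -1.15, and 3 rose when adjusted over the list alone (camera adjusted p = 0.446). Xyloglucan endotransglucosylases had 0 calls among 9, XTH26 at 0.97 and XTH29, at background in OsRR6ox, at -0.57, and 1 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.688). Among 8 cellulose synthase and related genes CSLC04 differed by 1.81 and CSLC12 by 0.51, 0 passed over all probe sets and 1 rose adjusted over the list alone. Camera gave that list an adjusted p of 0.167, with adjusted p = 0.589 with an estimated correlation and 0.460 from fry. It passed without OsRR6ox replicate 1, at the preset correlation, the only one run there. The histone genes HTB11 and HTB1 differed by 0.48 and 0.43, with 0 of 5 passing (camera adjusted p = 0.184), and the cell cycle genes AUR1, PRL and AUR2 by 0.18, 0.15 and 0.14.

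Markers of organs and cell types that a seedling can hold in different proportions were measured in small numbers. In the root epidermis and endodermis list EXPA7 rose, EXPA18 differed by 1.11, and PYK10 and NAI1 by -0.21 and -0.19. Adjusted over the list alone, 2 of these 4 rose. The meristem and boundary genes LAS, UFO and CLV3 differed by -0.19, -0.02 and -0.01, and the stomatal lineage genes SPCH, FMA and MUTE by 0.04, 0.02 and 0.00. LEA4-5 and OLEO3 of the seed list differed by -0.81 and -0.22, with 1 fall adjusted over the list alone, and the anther genes SPL and AMS by -0.09 and -0.08. UFO, CLV3, MUTE, SPL and AMS lay at array background on all 4 arrays and LAS on both OsRR6ox arrays, so their differences do not bear on organ proportions. Nitrate, phosphate, vascular, ethylene response factor, SAUR, aquaporin, cytosolic ribosomal protein and lipid transfer protein lists had 0 members matched to a probe set with a single gene name. This reflects the gene names used here, with 8730 probe sets unnamed, and does not show that the array lacks these genes.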

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

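The tests in this part were all chosen after the values had been seen. A control probe set of the array's Arabidopsis control group, which the comparisons do not use, was bright in OsRR6ox alone. It read 4.48 and 4.22 in the wild type and 12.81 and 13.31 in OsRR6ox, a difference of 8.71. The wild type values lie at array background, so this difference is a lower bound. Only 4 of the other 63 control probe sets were higher in both OsRR6ox arrays, which argues against a general rise of control signals. The probe set may detect a sequence carried by the transgene construct, which the difference of 8.71 allows but which cannot be told apart from other differences between the genotypes. Its name, AFFX-r2-At-U12639_at, points to a sequence U12639, but the sources used here do not say what that is or whether the construct holds it.

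Plastid and mitochondrial transcripts were lower in OsRR6ox in the values as deposited, with means of -0.52 and -0.39, but not after spike-in centring, with means of 0.0047 and 0.139. Scaling of all probe sets alike could thus set the sign of these means, but not the gap to other genes, since the plastid mean less that of all probe sets of the same array was 4.47 and 4.57 in the wild type and 4.02 and 4.03 in OsRR6ox, a difference of -0.49 with an SE of 0.05. Less RNA without a poly(A) tail in the labelled OsRR6ox material could lower plastid transcripts and ribosomal RNA together, and the 25S control differed by -1.75, from -0.48 to -3.02 with a wild type array left out, and 5S, at background in OsRR6ox, by -1.14 to -1.85. Between the wild type arrays 25S was higher in replicate 2 and 5S in replicate 1. The plastid median was higher in replicate 2 by 0.0946 relative to all probe sets, within 2 standard errors of 0.0633. That standard error is over 69 genes of a single pair of arrays. The genes are not independent replicates, so it holds no spread between arrays and cannot decide the question. The explanation by less RNA without a poly(A) tail stays open too. A change of organelle transcripts with OsRR6 also stays open, untested beyond the comparison itself.

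Some probe sets were at background in a single genotype and at least 8-fold brighter in the other. There were 16, 13 of them at background in the wild type, among them AT2G25510, AT1G23960 and CYP71B34, and AT3G48640 and AT5G04380 were at background in OsRR6ox. Quantile normalization, median centring and spike-in centring moved their differences by at most 0.53, against a smallest difference of 3.09 in size. These scalings are thus too small to make such differences. Because the probe sets were picked for a change of at least 8-fold, hardly any other outcome was possible. A difference in strain background or chromosome segments between the seed stocks might give such a pattern. A differing segment would place called genes side by side. A difference spread over the genome need not, so a count of neighbours cannot test it. Among all 171 called genes placed on the nuclear chromosomes, not these 16 probe sets alone, there were 3 neighbouring pairs moving the same way. The median of 10000 random draws was 1 (permutation p = 0.106, one-sided). The genes with the largest gaps between replicates gave 3 pairs in the wild type and 4 in OsRR6ox. Only pairs moving the same way were counted, and genes of a differing segment need not do so. Strain and transgene thus cannot be told apart with these arrays.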

How the results depend on the processing

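All 296 calls kept their sign in every setting in which they were tested. Spike-in centring and the setting without on and off probe sets were chosen after seeing the data. Most settings could not have reversed a sign, so this is no evidence of robust calls. The arrays of all 296 did not overlap, so leaving out an array cannot reverse one. Variance models, thresholds and filters leave the differences as they are. Spike-in controls differed by -0.53 on average, and the smallest called change was 0.88 in size. The count of changed probe sets (296, 185 up and 111 down) was 370 under quantile normalization, 390 with a variance trend, 292 with robust eBayes, 312 with array weights, 345 without the dimmest 25%, 281 with a 2-fold minimum and 266 without on and off probe sets. It moved by over 1.5 times under median centring (492, 283 up and 209 down), without the dimmest 50% of probe sets (102, 62 and 40), at adjusted p under 0.01 (64, 48 and 16) and under 0.1 (673, 370 and 303), and under spike-in centring (3013, 2863 and 150), a fit with a common SD for all probe sets whose calls are not comparable with the others. The cause was not tested for median centring and the dim probe sets. Leaving out each array in turn gave 45 to 465 calls, 35 to 217 up and 9 to 248 down, where the lone array of a genotype is assumed to vary like the other pair. The replicate number as a block gave 105 calls (76 up and 29 down, 98 of them shared, and 0 of the 3 subtilase genes) with fewer residual degrees of freedom. The labels do not say that a number marks a shared day, and deviations of same-numbered arrays correlated at 0.259 across probe sets.

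The 29 named genes kept their direction in every setting that tested them, which for the same reason is no evidence of robust calls. Of them 7 passed under the block, 28 with a trend or robust eBayes and 26 under spike-in centring. The 2 lists that shifted became 0 with an estimated correlation and 0 with fry, which tests against no change, and stayed 2 in the other settings, except 3 without OsRR6ox replicate 1. Median centring and spike-in centring shift all genes of an array alike, so they could hardly change which lists passed a test against other genes. That the lists passed under these 2 settings is thus no evidence of robust lists. Spike-in centring, which shifts all probe sets, turned the chloroplast-encoded genes mean log2 difference to 0.0047 and the mitochondrion-encoded genes mean log2 difference to 0.139. For genes at array background in a genotype, such as CYP71B34 and FHL in the wild type and ndhF in OsRR6ox, the background limits the size of a difference that can be measured.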

Other observations

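Symbol families were screened for an excess of called genes after the values had been seen. Among 1466 nuclear genes with a symbol, 23 of them called, 45 symbol families had at least 5 measured genes, and SBT alone passed, with 2 rises and 1 fall among 8 measured genes (Fisher's exact test, one-sided, adjusted p = 0.00809), SBT4.12, ATSBT5.2 and SBT3.12. That excess rests on 3 calls, of which 0 passed without OsRR6ox replicate 1 (limma adjusted p of 0.0759 to 0.145) or without OsRR6ox replicate 2 (0.103 to 0.175), and 2 passed when either wild type array was left out. The UGT glycosyltransferases had 1 rise and 2 falls among 47 (adjusted p = 0.785). Called genes lay on all 5 chromosomes, at 1.14% to 1.43% of those measured.

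The genes in this paragraph were chosen after their gaps between replicates were seen, and no enrichment was tested. BHLH101, of the iron list, read 5.19 in wild type replicate 1 and 9.47, 9.56 and 10.41 on the other arrays, while PYE of the same list read 6.71 and 7.98 and AT3G13610 8.63 and 8.23 in wild type replicates 1 and 2. AT1G47400, which encodes an IRON MAN peptide, read 7.57 there and 11.15 in wild type replicate 2, and AT4G36700 read 4.27 against 7.95, 8.20 and 9.32. In all, 7 probe sets differed at least 8-fold between the wild type arrays and 1 between the OsRR6ox arrays. EXO, EXLA1 and XTH18 differed more between the OsRR6ox arrays, where replicate 2 was higher by 2.35, 2.37 and 1.92, than between the wild type arrays, where it was higher by 1.58, 1.21 and 0.55.

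An unnamed probe set rose from array background, 4.15 and 4.24 in the wild type, to 11.78 and 11.58 in OsRR6ox, a difference of 7.49 and a lower bound. Of the 185 probe sets that rose, 42 (22.7%) started at array background in the wild type, and 18 of the 111 that fell (16.2%) reached background in OsRR6ox (Fisher's exact test, two-sided, p = 0.232). Spike-in controls, which standard protocols add in fixed amounts, differed by -0.53 on average, OsRR6ox minus wild type. Single controls differed by -0.13 to -0.91, and 38 of 42 were lower in both OsRR6ox arrays.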
